A study of Mus musculus with 6 samples.

How the data were processed

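RNA-seq was analysed from 3 libraries of neonatal mouse cardiac fibroblasts infected with a scramble hairpin and 3 infected with a hairpin against Cfast, grouped by the labels. Per the labels' protocols, poly(A) RNA was selected with oligo-dT beads and libraries were made with a kit for which no strand information is given. Whether reads of overlapping antisense genes were told apart is therefore not known. The labels describe cultured cells in some fields and ventricular tissue in the extraction protocol; the cell type field was followed. STAR 2.5.1b, DESeq2 1.10.1 and genome build mm9 are named per the submitters' processing notes. The gene counter, annotation and filters are not given in the sources used here. The gene coordinates in the deposited table are not those of mm9: of 5563 gene identifiers also in GENCODE vM21 (GRCm38), 5338 (96.0%) had identical chromosome, start, end and strand there, so coordinates are given as GRCm38.

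The single deposited table holds, for each gene and library, a signal in normalized counts, which the authors made by dividing gene counts by a size factor per library. Its log2 fold changes, per the file headers, and its p-values and adjusted p-values are the authors' own comparison of the groups. It lists 5565 genes, 3023 higher and 2542 lower in the authors' deposited table, all with a deposited adjusted p of at most 0.0500. The relation of the deposited p-values to their ranks gave 17251 tested genes, so the table holds 32.3% of them. The other genes could not enter any comparison. Selection by the outcome means that the share of called genes, the spread of unchanged genes and the scaling of the full libraries cannot be judged from the table. Tests here adjusted p-values by Benjamini-Hochberg over 17251 genes, treating those not listed as not significant.

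Values of each library were whole multiples of a single step, so whole reads could be recovered for 100% of values (tolerance 0.1 read). Recovered reads over the listed genes came to 14120034, 10229668 and 15556916 in control replicates 1, 2 and 3 and to 13311259, 11843855 and 10338828 in knockdown replicates 1, 2 and 3; the full depth of the libraries is not known. Counts within each group differed by more than sampling noise in every pair (chi-square per gene from 4.66 to 89.0), so all libraries were counted as separate samples.

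Because the values are normalized, limma (version 3.58.1, with a mean-variance trend, in R 4.3.3) was applied to log2(normalized count + 1), without a filter, to compare Cfast knockdown with scramble control. The log2 changes are on that scale, which understates the change of low genes. A gene was called at an adjusted p under 0.05. Normalized counts are given as mean ± SD and log2 changes as estimate ± SE. The design had assumed a table of all genes. It was not changed, and the tests compare only listed genes. On simulated data with the same 5565 genes and their control means, 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. This test of Cfast knockdown against scramble control recovered 35.8%, 79.1% and 100% of them, with 3 false calls. Far fewer genes changed there than were called in the data, which makes the adjusted threshold stricter. These shares therefore do not measure the power in the data.

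There were 16 gene lists and 8 cell type marker lists. Those with at least 5 listed members were compared with the other listed genes by camera in limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 22 lists tested; the alternative estimated the correlation. For counts adjusted over the list alone, members not listed were treated as not significant. Genes named in the text are Cfast, Cotl1 and Trap1, the 12 higher and 12 lower called genes with the largest log2 change among those with a mean at or above the median and no overlap between groups, leaving out predicted genes, clone names and pseudogenes, up to 4 members per list with the smallest adjusted p, and a set of fibrosis genes (Col1a1, Col1a2, Col3a1, Fn1, Postn, Acta2, Tagln, Ctgf and Tgfb1). Some genes that this rule takes are not reported here. The groups, lists, main test and this rule were chosen before the data were examined. Other genes are said to have been named after their values were seen.

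Alternatives were quantile normalization, limma-voom and DESeq2 (version 1.42.0) on the recovered reads, a filter of at least 5 normalized counts in 3 libraries, a minimum log2 change of 1, a pseudocount of 0.1, the replicate number as a block, and each library left out in turn. Added after the data were seen were edgeR (version 4.0.16) on the recovered reads, TMM scaling over the listed genes, adjustment over the listed genes alone, and removal of a lowess trend on log2 gene length from each library. The remaining summaries were made in Python 3.11.15 with pandas and scipy. Gene lengths are those of the deposited table.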

Results

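Poly(A)-selected RNA was sequenced from neonatal C57BL/6 mouse cardiac fibroblasts, the matrix-producing cells of the heart, grown in 10% serum. The cells had been infected for 24 hours, at a multiplicity of infection of 50, with a lentivirus carrying a short hairpin RNA against the long noncoding RNA Cfast or a scramble hairpin, and RNA was taken after 72 hours. There were 3 scramble control and 3 Cfast knockdown libraries. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. The authors' deposited table gave normalized counts of 5565 genes, all with a deposited adjusted p under 0.05, out of 17251 genes behind that adjustment. Between 10229668 and 15556916 reads per library fell on the listed genes. The other 11686 genes were not analysed here. A gene described below as not listed has no value here. It either missed the authors' threshold or was not tested by them under that name.

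The comparison of the groups asked which transcripts changed when Cfast was knocked down. In the knockdown, acute-phase and chemokine genes such as Saa3, C3, Ccl2 and Ccl7 rose together with the secreted phosphoprotein gene Spp1, while elastin (Eln), tenascin C (Tnc) and several collagen genes fell. C3, the central complement component, rose from 4506 ± 1279 to 66463 ± 3423 normalized counts (mean ± SD, n = 3 libraries per group). Spp1 rose 8.62-fold, from 10136 ± 1239 to 87365 ± 25776. Eln fell from 592713 ± 29052 to 219073 ± 50077, or from 4.95% ± 0.213 to 1.73% ± 0.462 of the normalized counts of listed genes (SD, n = 3). Among called genes with a mean at or above the median of the listed genes and no overlap between groups, leaving out genes with predicted or clone names and pseudogenes, the 12 higher genes with the largest changes were Saa3, Serpina3n, Cxcl5, C3, Ccl7, Ccl2, Ccl6, Spp1, Lbp, Fabp4, Adam8 and Cfp, with log2 changes from 2.44 to 5.06 and limma adjusted p from 1.41e-05 to 4.14e-04. By the same rule the 12 lower genes were Angptl7, Scg2, Col15a1, Col6a3, Col4a4, Tnc, Nrep, Col27a1, Eln, Plxna4, Ttn and Heyl, with log2 changes from -2.18 to -1.42 and adjusted p from 1.07e-04 to 0.00625. Reads of Saa3 and Serpina3n can be shared with close paralogs, so their levels are uncertain, and Saa3 stood at 16259 normalized counts in knockdown replicate 1 against 5068 and 4883 in the others. With quantile normalization Eln kept its direction but not its call (log2 change -0.58, limma adjusted p = 0.590). Without the trend on gene length Ttn did the same (-0.20, limma adjusted p = 0.346). Quantile normalization gives each rank the same value in every library, and Eln was among the highest listed genes in both groups. That setting can therefore shrink a fall of Eln and cannot judge its size.

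In GRCm38 coordinates, C3 (ENSMUSG00000024164) lies on chromosome 17 from 57203970 to 57228136, Spp1 (ENSMUSG00000029304) on chromosome 5 from 104435118 to 104441050, and Eln (ENSMUSG00000029675) on chromosome 5 from 134702593 to 134747323. All 3 are protein-coding genes. The values are given per gene, and which parts of a gene were counted is not known.

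No listed gene carries the name Cfast and the labels give no identifier for it, so the knockdown itself was not analysed here. Cotl1, which encodes the actin-binding coactosin-like protein (ENSMUSG00000031827, chromosome 8, 119809222 to 119840544), rose 2.01-fold, from 3295 ± 160 to 6635 ± 762 normalized counts (n = 3; limma log2 change 1.00 ± 0.10 SE, adjusted p = 4.75e-04). Trap1, a mitochondrial chaperone gene, was not listed.

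Over all listed genes, limma called 2413 genes higher and 2032 lower in the knockdown, 4445 in all, of which 1068 changed by at least 1 on the log2 scale (611 higher, 457 lower). In 5428 of the 5565 listed genes (97.5%) the 3 knockdown libraries did not overlap the 3 controls, where chance gives 10%, but the table holds only genes that had already passed the authors' test. The median log2 change of all listed genes was 0.31 with the deposited size factors. Higher genes made up 54.3% of the calls with these factors, 41.1% after quantile normalization, which moved the median log2 change by -0.10, and 44.9% with TMM scaling over the listed genes. The count fell to 2767 without control replicate 1, to 1869 without control replicate 2, to 1904 without control replicate 3 and to 2457 without knockdown replicate 3.

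**Figure D1:**
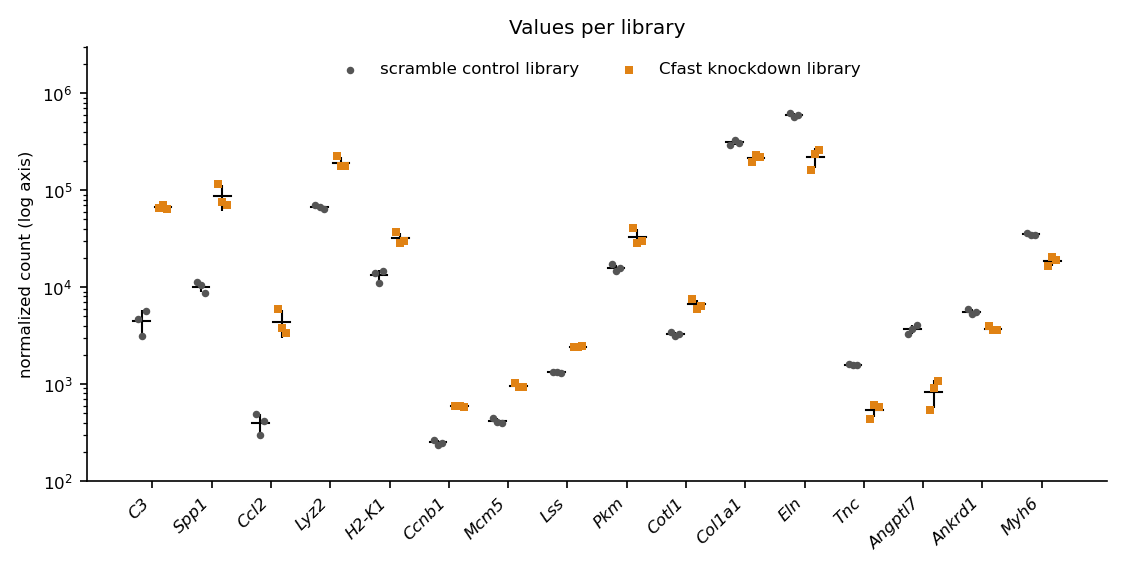
Normalized counts (log axis) of 16 genes in each scramble control library (circles) and each Cfast knockdown library (squares), with the mean (horizontal line) and SD (vertical line) of 3 libraries. C3 lies between 3164 and 5709 in the controls and between 63913 and 70353 in the knockdown, while Eln lies between 562302 and 620182 in the controls and between 162626 and 258161 in the knockdown.

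Inflammatory genes rose in the knockdown. Of the 44 genes on the list of inflammatory cytokines and NF-kB targets, 34 were listed, 32 were called higher and none lower, with a median log2 change of 1.48. Adjusted over the list alone, 33 were higher and 1 lower. Cxcl5, a neutrophil chemoattractant, rose by 3.95 ± 0.26 (log2 ± SE, n = 3), Ccl2, which attracts monocytes, by 3.43 ± 0.24, and Steap4, a metalloreductase gene, by 3.03 ± 0.21, with limma adjusted p from 1.07e-04 to 1.18e-04. The list stood above the other listed genes in camera (adjusted p = 3.63e-08), a call that was lost with adjusted p = 0.365 with an estimated correlation. Of the 53 interferon response genes, 18 were listed, 17 were called higher and 1 lower (Eif2ak2, -0.44, named after its value was seen), the same numbers as when adjusted over the list alone, with a median of 0.87 (camera adjusted p = 0.00129; adjusted p = 0.511 with an estimated correlation). Without the trend on gene length the median of the interferon list was 0.55. Of all tested genes 32.3% were listed, a share near that of this list. The mean of its listed members had an SD of 0.222 among the control libraries, the largest of the 22 lists. The members with the smallest p were antigen presentation genes, H2-D1, H2-K1, Psmb8 and B2m, whose log2 changes lay between 0.97 and 1.27. Reads of H2-D1 and H2-K1 can be shared with paralogs.

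Markers of macrophages and leukocytes moved with these groups. Of 21 such markers 19 were listed and 18 were called higher (19 higher when adjusted over the list alone), with a median log2 change of 0.96 (camera adjusted p = 1.27e-05; adjusted p = 0.365 with an estimated correlation). Itgam, an integrin subunit of myeloid cells, rose 4.85-fold, from 480 ± 47.2 to 2329 ± 279.7 normalized counts, and Lyz2, the macrophage lysozyme, rose 2.86-fold, from 67158 ± 2695 to 192349 ± 27713 (n = 3). Without the trend on gene length the median of the markers was 0.53. The controls already held Lyz2 at 21.6% of the level of Col1a1, against 89.0% in the knockdown. Reads of Lyz2 can be shared with its paralog Lyz1, which rose by 0.66, is on the same list and was named after its value was seen.

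Genes of cell division rose throughout. All 36 listed members of the 40 mitotic genes were called higher, with a median of 0.90 and none below 0.44, and all 37 listed members of the 43 DNA replication genes, with a median of 0.80 and a range from 0.42 to 1.82. Adjusted over the list alone the counts were again 36 and 37. Ccnb1, the cyclin of mitotic entry, rose from 250 ± 13.98 to 588 ± 5.65 normalized counts, and Mcm5, a subunit of the replicative helicase, from 415 ± 25.7 to 964 ± 45.2 (n = 3). Mki67 and Top2a rose by 0.97 ± 0.09 and 0.88 ± 0.08 on the log2 scale, and E2f2, Rrm2 and Cdt1 by 1.82 ± 0.13, 1.34 ± 0.10 and 1.49 ± 0.11 (SE, n = 3). Each list had a camera adjusted p of 1.97e-08, and each an adjusted p = 0.338 with an estimated correlation.

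Matrix genes fell. Of the 50 extracellular matrix genes, 35 were listed, 29 were called lower and 1 higher (Fbln1, 0.36, named after its value was seen), with a median of -0.61. Adjusted over the list alone, 30 were lower and 1 higher. Col15a1 fell by 1.79 ± 0.15, Tnc by 1.55 ± 0.13 and Cthrc1 by 0.86 ± 0.09 (log2 ± SE, n = 3). The fibrillar collagen gene Col1a1 fell from 310695 ± 19036 to 216216 ± 17230 normalized counts (log2 change -0.52 ± 0.13, limma adjusted p = 0.0226), and Col1a2 fell by 0.49 ± 0.12. Quantile normalization left Col1a1 at -0.070 and Col1a2 at -0.16, and removal of the trend on gene length left them at -0.25 and 0.078, and neither was called in these settings. Both were among the highest listed genes in each group, where quantile normalization can shrink a change, as for Eln. Calls for both were also lost without any of control replicates 1, 2 or 3 or knockdown replicate 3, which gave Col1a1 between -0.56 and -0.48 and Col1a2 between -0.50 and -0.48. Col3a1, Fn1 and Postn were not listed, so no change past the authors' threshold is known for them. The list lay below the other listed genes (camera adjusted p = 5.05e-07; adjusted p = 0.365 with an estimated correlation). Long genes were lower as a whole, and without the trend on gene length the median of the list was -0.31. Cardiac fibroblast markers fell as well (median -0.50). A smaller share of fibroblast RNA and a lower level of matrix transcripts per fibroblast therefore cannot be told apart here.

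Among 45 genes of TGF-beta signalling, the main profibrotic pathway of fibroblasts, 30 were listed, 19 were called lower and 7 higher, and 21 and 9 when adjusted over the list alone (median -0.42; camera adjusted p = 0.0308; adjusted p = 0.365 with an estimated correlation). Cotl1 and Trap1, reported above, had also been placed on this list, and Cotl1 is among the 7 called higher. The latent binding protein gene Ltbp1 fell by 0.87 ± 0.10 and the feedback inhibitor gene Pmepa1 by 0.64 ± 0.09, whereas the transcription factor gene Junb rose by 1.62 ± 0.12 and the ligand gene Tgfb1 by 0.66 ± 0.09. YAP/TAZ targets, which report mechanical and Hippo signals, had 12 of 24 listed, with 8 lower and 1 higher (9 and 1 when adjusted over the list alone) and a median of -0.46 (camera adjusted p = 0.00838; adjusted p = 0.365 with an estimated correlation). Ankrd1 fell by 0.58 ± 0.09, Ccdc80 by 0.50 ± 0.08 and Tead1, a partner of YAP rather than a target alone, by 0.59 ± 0.11, a change that was 0.0079 without the trend on gene length. The higher member was Gadd45a, at 0.53 ± 0.11, a call that was lost without control replicate 2 (0.51), without control replicate 3 (0.49) and without the trend on gene length (0.09). Ctgf stood at -0.25 ± 0.09 (adjusted p = 0.0803), and passed the threshold with quantile normalization (-0.38), with TMM scaling (-0.33), with DESeq2 (-0.25), with adjustment over the listed genes alone and without the trend on gene length (-0.52).

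The lists of the contractile apparatus, collagen processing and matrix proteases did not stand apart from the remaining listed genes in camera. For the myofibroblast contractile apparatus 16 of 37 were listed, 10 called lower and 4 higher (10 and 5 adjusted over the list alone; median -0.35, or 0.052 without the trend on gene length; camera adjusted p = 0.111). Smtn and Myh11 fell by 0.57 ± 0.09 and 0.82 ± 0.16, the latter to -0.46 without the trend on gene length. Tpm4 rose by 0.46 ± 0.09, a call that was lost without control replicate 2 (0.43), without control replicate 3 (0.47) and without the trend on gene length (0.078). Acta2 and Tagln were not listed, so for them too no change past the authors' threshold is known. For collagen processing and crosslinking 9 of 23 were listed, 5 called lower and 2 higher (5 and 4 adjusted over the list alone; median -0.40, adjusted p = 0.428), with Pcolce2 lower by 1.04 on the log2 scale (-1.04 ± 0.11) and the transglutaminase gene Tgm2 higher (0.66 ± 0.09). For matrix proteases and their inhibitors 25 of 42 were listed, 15 called higher and 9 lower (15 and 10 adjusted over the list alone; median 0.45, or 0.22 with quantile normalization; adjusted p = 0.321). The metalloproteinase genes Adam8 and Mmp12 rose by 2.57 ± 0.09 and 2.23 ± 0.19, and the urokinase gene Plau and its receptor gene Plaur by 1.38 ± 0.09 and 1.45 ± 0.14. The protease list shares Ctss with the macrophage markers, which also rose, and which cells carry these changes was not measured.

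**Figure D2:**
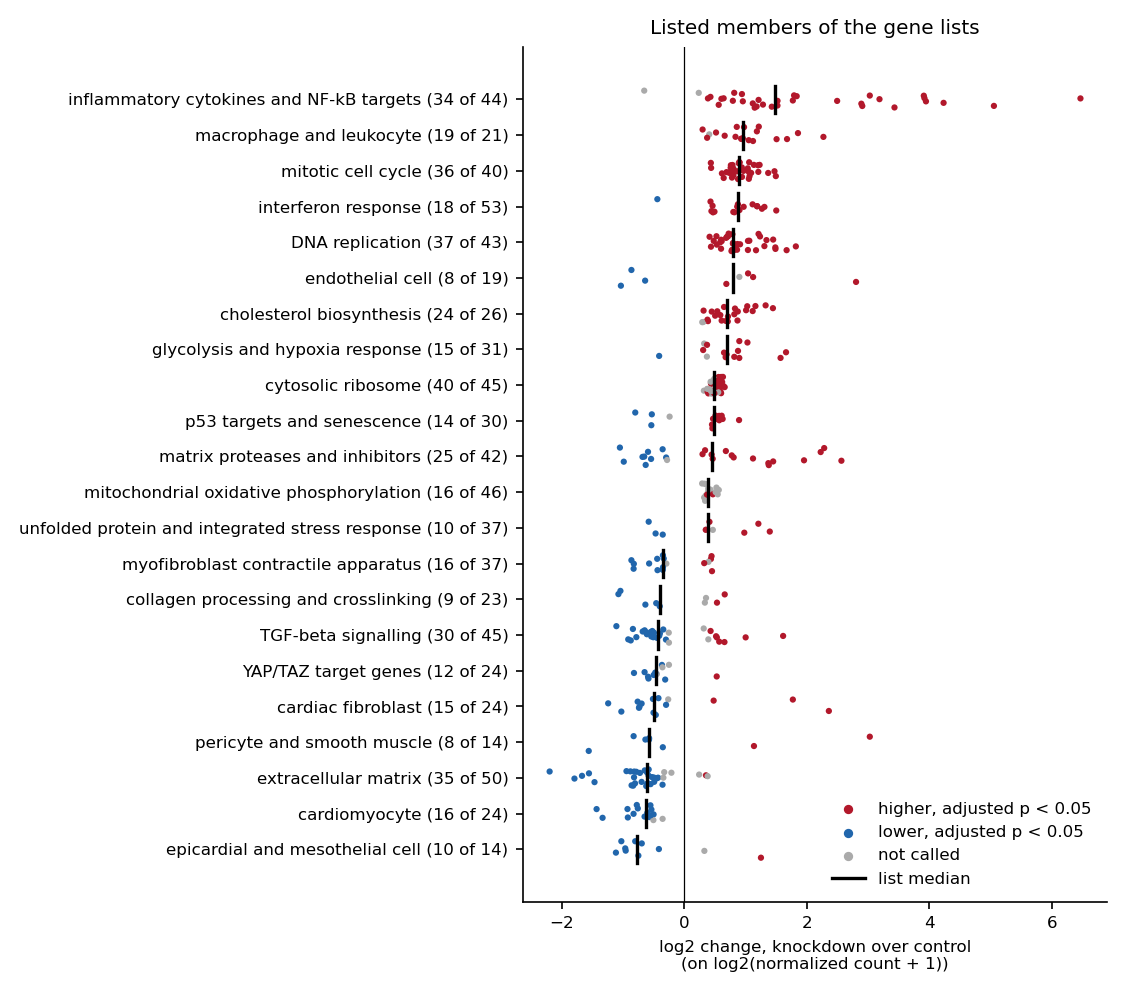
Log2 change (knockdown over control, on log2(normalized count + 1)) of each listed member of 22 gene and marker lists, with the list median as a black line and, in brackets, how many members of each list were listed. Red and blue points were called higher or lower by limma at an adjusted p under 0.05, and medians run from -0.77 for epicardial and mesothelial markers to 1.48 for inflammatory genes; none of the lists passes with an estimated correlation, and those of oxidative phosphorylation and the myofibroblast apparatus change sign without the trend on gene length.

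Sterol and glycolytic enzymes rose. All 24 listed members of the 26 cholesterol biosynthesis genes had positive changes, 22 were called higher and 24 when adjusted over the list alone, with a median of 0.70 (camera adjusted p = 2.02e-05; adjusted p = 0.338 with an estimated correlation). Lanosterol synthase (Lss) rose from 1320 ± 22.4 to 2414 ± 37.0 normalized counts (n = 3). Of 31 genes of glycolysis and the hypoxia response 15 were listed, 12 were called higher and 1 lower (Egln3, -0.41, named after its value was seen), the same numbers as when adjusted over the list alone, with a median of 0.69 (camera adjusted p = 0.009998; adjusted p = 0.553 with an estimated correlation). Knockdown replicate 1 stood apart, with a mean change of the listed members of 1.05 against 0.54 and 0.57 in the others, and the median without it was 0.50. Pkm, the pyruvate kinase gene, rose 2.07-fold, from 15898 ± 1185 to 32892 ± 6490 (n = 3).

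Short genes were higher and long genes lower in the knockdown. In the fifth of the listed genes with the shortest deposited lengths (57 to 2152 bp) 84.7% were higher, and in the fifth with the longest (8113 to 116825 bp) 15.5%, with a Spearman rho of -0.42 across genes, which are not independent replicates. Genes of short transcripts rose with this trend: of the 45 cytosolic ribosome genes 40 were listed, 28 were called higher and none lower (40 higher when adjusted over the list alone), with a median of 0.49 (camera adjusted p = 3.74e-04; adjusted p = 0.566 with an estimated correlation). This median was 0.29 with quantile normalization and 0.33 without knockdown replicate 1, since the mean change of the listed members was 0.83 in that library against 0.24 and 0.45 in the others. Without the trend on gene length it was 0.10 and the call was lost (adjusted p = 0.414). The named members Rpl37, Rpl19, Rpl32 and Rpl35 rose by 0.60 to 0.64, calls that were lost without control replicate 2, where they lay between 0.56 and 0.60, without control replicate 3 (0.57 to 0.61) and without knockdown replicate 3 (0.63 to 0.67), and reads of such genes can be shared with processed pseudogenes. Of the 46 oxidative phosphorylation genes 16 were listed, 2 were called higher (Cox6a1 and Uqcrb, both lost with quantile normalization and without any of the controls or knockdown replicate 3) and the median was 0.39. Adjusted over the list alone limma called 0, with 16 at an unadjusted p under 0.05, and the count tests over all genes called 4 (edgeR) and 11 (DESeq2). The list's camera call (adjusted p = 0.0328; adjusted p = 0.566 with an estimated correlation) ended without control replicate 2 (adjusted p = 0.0681), control replicate 3 (0.0505) or knockdown replicate 1 (0.0534), and without the trend on gene length (adjusted p = 0.153), where its median was -0.051. The median was 0.23 without knockdown replicate 1, in which the mean change of the members was 0.73 against 0.17 and 0.34 in the others.

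**Figure D3:**
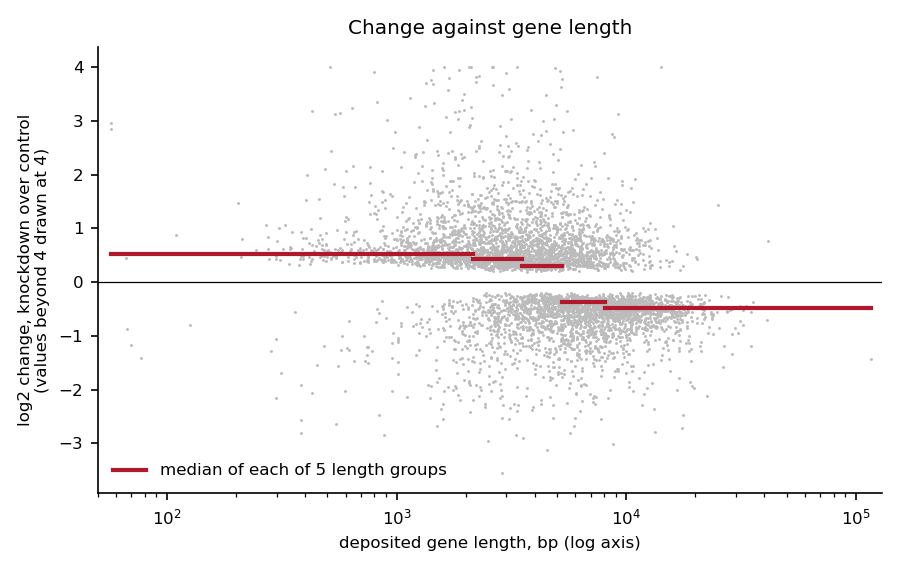
Log2 change of each listed gene (knockdown over control) against its deposited gene length in bp on a log axis, with the median of each of 5 groups of genes by length as a red line. The medians are 0.53, 0.43, 0.31, -0.37 and -0.48 from the shortest to the longest genes, and the gap around 0 reflects that only genes past the authors' threshold were listed.

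Stress lists were mixed. Of 30 p53 target and senescence genes 14 were listed, 10 were called higher and 3 lower (10 and 4 when adjusted over the list alone; median 0.49, camera adjusted p = 0.254), with Cdkn1a and Mdm2 higher by 0.51 ± 0.09 and 0.52 ± 0.09, Fas by 0.90 ± 0.12, and Perp lower at -0.80 ± 0.10. Of 37 genes of the unfolded protein and integrated stress response 10 were listed, 5 were called higher and 3 lower, also when adjusted over the list alone (median 0.39, camera adjusted p = 0.373). The medians of these lists were 0.18 and 0.083 once the trend on gene length was removed. The stress transcription factor genes Atf3 and Cebpb rose by 1.40 ± 0.10 and 1.21 ± 0.15, and the amino acid transporter gene Slc7a5 fell by 0.58 ± 0.09.

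Markers of the other cell types of the heart moved in different directions. Of 24 cardiomyocyte markers 16 were listed, 14 were called lower (16 when adjusted over the list alone), with a median of -0.62 (camera adjusted p = 2.39e-05; adjusted p = 0.338 with an estimated correlation). Myh6, the cardiac myosin heavy chain, fell from 35106 ± 1135 to 18571 ± 2089 normalized counts (n = 3), which was 11.3% of the level of Col1a1 in the controls and 8.59% in the knockdown. Of 24 cardiac fibroblast markers 15 were listed, 11 were called lower and 3 higher, also when adjusted over the list alone, with a median of -0.50 (camera adjusted p = 0.0163; adjusted p = 0.365 with an estimated correlation). The median of the fibroblast markers was -0.31 once the trend on gene length was removed. Meox1 and Islr fell by 1.24 ± 0.17 and 0.76 ± 0.11, and the higher members included Ly6a (2.36 ± 0.31) and S100a4 (1.77 ± 0.26), both also known from other cell types. Of 14 epicardial and mesothelial markers 10 were listed, 8 were called lower and 1 higher (8 and 2 when adjusted over the list alone), with a median of -0.77 (camera adjusted p = 0.0181; adjusted p = 0.365 with an estimated correlation). Gpm6a, Krt7 and Upk3b fell by 0.96 ± 0.10, 0.95 ± 0.13 and 1.02 ± 0.15, and Rarres2, which encodes a chemoattractant of macrophages, rose by 1.25 ± 0.14. Endothelial markers (8 of 19 listed, 4 higher and 3 lower, 5 and 3 adjusted over the list alone, camera adjusted p = 0.507) and pericyte and smooth muscle markers (8 of 14 listed, 2 higher and 6 lower, also adjusted over the list alone, camera adjusted p = 0.189) went both ways, with medians of 0.80 and -0.57, or 0.51 and -0.34 without the trend on gene length. Only 1 of 9 Schwann cell markers (Cnp, 0.36) and none of 12 erythroid markers was listed, too few to test.

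Camera placed 15 of the 22 tested lists past the threshold with the preset inter-gene correlation of 0.01. With an estimated correlation camera called 0 of them, and 0 had an unadjusted p under 0.05, the lowest being 0.0519. That setting also takes its degrees of freedom from the libraries rather than from the genes. It therefore differs from the preset setting in more than the correlation, and the lost calls do not measure correlation alone. Every list was compared only with other genes that the authors' test had already selected.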

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

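The edgeR, TMM and gene length alternatives and the adjustment over the listed genes alone were chosen after seeing the data; the others were planned. Against 4445 called genes (2413 higher, 2032 lower), the count was 4228 with quantile normalization, 4442 with the stricter filter, 4403 with the smaller pseudocount, 4528 with limma-voom, 5214 with DESeq2 and 4526 with edgeR on recovered reads, 4296 with TMM over the listed genes and 5557 adjusted over the listed genes alone. Having no filter was already the main setting, so that alternative gave no further value. None of the genes called both in the main setting and with quantile normalization, TMM, edgeR or DESeq2 changed direction. A minimum log2 change of 1 left 1068 genes (611 higher, 457 lower) by its construction. Leaving out a library gave 1869 to 5034 genes, 1188 to 2743 higher and 681 to 2291 lower, with 2767 without control replicate 1, 1869 without control replicate 2, 1904 without control replicate 3 and 2457 without knockdown replicate 3; fewer libraries raise the p-values, but counts rose to 4652 and 5034 without knockdown replicates 1 and 2, which stood farthest from their group mean. Without the trend on gene length 3018 genes were called, 1262 of them lower, and 31 called in both settings changed direction. That setting also turned the median of oxidative phosphorylation to -0.051, of the myofibroblast apparatus to 0.052, and the log2 changes of Cox6a1 to -0.069, Uqcrb to -0.15, Tead1 to 0.0079 and Col1a2 to 0.078, and it ended the camera calls of oxidative phosphorylation and the cytosolic ribosome (median 0.10). Camera called 15 lists in the main setting, 14 to 15 when a library was left out, 13 without the length trend and 0 with an estimated correlation. The cause was not tested. Of the 105 named genes with values, 98 kept direction and side of the threshold with quantile normalization, 90 without control replicate 2, 90 without control replicate 3, 93 without knockdown replicate 3 and 90 without the length trend.

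With the replicate number as a block 5533 genes were called (against 4445), and no list changed its side of the threshold; of the 105 named genes, Ctgf alone did, and passed it (log2 change -0.25, adjusted p = 0.0246). Same-numbered libraries deviated together with correlations of 0.504, 0.349 and 0.0751 for numbers 1, 2 and 3. Pairs of unlike number ranged from -0.490 to 0.175, so some lay above the pair of number 3. Deviations from a shared group mean are tied to each other, so these correlations are not independent. Of 6 libraries, 4 correlated best with their own number. The labels state no pairing, so the main test did not pair the samples. A source of variation shared by libraries of the same number stays possible. In simulated data with 3 libraries per group, 35.8% of 1.5-fold changes were recovered. Far fewer genes changed there than were called in the data, so this share does not measure the power in the data. The part that depth plays in this was not tested, and genes that the authors' test did not select have no values here.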

Other observations

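The gene families in the first paragraphs and all tests below were chosen after the values were seen, except that the tests of gene length (apart from its slopes), and of list membership as its source, were set out before their results. Across 16 families picked by symbol or by function, the direction of listed members was compared with that of the other listed genes by Fisher's exact test, two-sided and adjusted over the families. Members of a family are not independent, and families picked after seeing the values make these p too small. No p is given for the 3 families put together by hand (acute-phase, lipid-associated macrophage and Notch pathway genes), since some of their members had been seen to change. All 8 listed acute-phase genes were higher (median log2 change 4.34), among them the iron-binding lipocalin Lcn2, which rose from 5.80 to 739 normalized counts, and haptoglobin (Hp), from 9.69 to 1165. All 16 chemokine genes (median 2.70, adjusted p = 1.37e-04), 16 major histocompatibility genes (1.19, adjusted p = 1.37e-04) and 14 serpin genes (1.47, adjusted p = 4.18e-04) were higher, although reads of the clustered Serpina3 and H2 genes can be shared between copies. All 6 cathepsin genes were higher (median 0.97, adjusted p = 0.0427), with Ctsd rising from 35557 to 84035 normalized counts, as were 16 of 18 genes of the vacuolar proton pump, which acidifies lysosomes (0.51, adjusted p = 0.00523; by limma 14 called higher and 1, Atp6v0e2, lower at -0.54), and all 12 listed genes of a lipid-associated macrophage set (0.93; 11 called), including Lgals3 (1.95), Fabp5 (1.72) and Gpnmb (0.99). Such genes are expressed in many cell types, and which cells carry these changes was not measured.

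Of 27 listed collagen genes 25 were lower (median -0.72, adjusted p = 1.56e-06), and of 19 potassium channel genes 14 were lower (-0.78, adjusted p = 0.0255), while Kcnn4 and Kcnab2 rose by 1.76 and 1.68. Zinc finger genes named Zfp were lower in 74 of 83 cases (median -0.46, adjusted p = 5.23e-16), and limma called 58 lower and 6 higher. All 71 ribosomal protein genes, 37 mitochondrial ribosomal protein genes and 22 proteasome subunit genes had positive changes. Their medians were 0.52, 0.48 and 0.40, against 0.31 over all listed genes, and limma called 50, 21 and 11 of them. Without the trend on gene length the medians of these 3 families were 0.090, 0.10 and 0.13, those of the collagen and Zfp genes -0.33 and -0.22, and that of the proton pump genes 0.32. C-type lectins (adjusted p = 0.0825) and semaphorins and plexins (adjusted p = 0.0571) missed the threshold. Of the Notch pathway genes Hey1 (-1.43) and Heyl (-1.42) fell and Rbpj rose (0.78); without the length trend the medians of the semaphorin and Notch families went from -0.50 and -0.54 to -0.11 and -0.15. No family changed the sign of its median with quantile normalization, TMM scaling over the listed genes or removal of the length trend.

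Macrophage and leukocyte markers were higher in the knockdown by a median log2 of 0.96. A larger share of macrophages alone would raise all markers by a common factor if only macrophages expressed them. The SD of their changes (0.52) was 3.99 times their median SE, from Csf1r at 0.30 to Itgam at 2.27. Without the trend on gene length it was 8.22 times. Whether other cells express some of the markers was not measured, so the spread cannot exclude a larger share alone. A lower share of fibroblasts that raised every other cell type alike would raise cardiomyocyte markers, whereas these fell by a mean of 0.73 (log2 change -0.734 ± 0.0656 SE). Fibroblast and mesothelial markers fell too (medians -0.50 and -0.77). A fall of several cell types beside more macrophages is therefore not excluded. Gene length may account for a part, since removing its trend lowered the median to 0.53, yet that median stayed far above 0 (SE of the mean of the markers over libraries 0.0276), which argues against length as the whole source. Activation of macrophages together with a larger number of them, through the knockdown or through the response to the hairpin, stays open as a hypothesis and was not tested.

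Short genes were higher and long genes lower in the knockdown, with a Spearman rho of -0.42 across genes (-0.36 without knockdown replicate 1). The trend also held outside the gene lists, with a rho of -0.418 over the 5124 genes that are on none of them. Only 441 listed genes are on a list, so leaving them out could hardly have moved rho. A length bias of single libraries is a candidate explanation. Within the groups, knockdown replicate 2 deviated from its group mean with a rho of 0.612 and knockdown replicate 1 with -0.60, and control replicate 1 with -0.51. Control replicates 2 and 3 and knockdown replicate 3 deviated with 0.37, 0.29 and 0.27. Libraries of the same number shared the sign, but deviations from a shared group mean are tied to each other, so these signs are not independent. The slope of log2 level on log2 length differed between the groups by -0.281 ± 0.0680 (SE, n = 3) and spanned 0.216 within the knockdown and 0.0783 within the controls, so such a bias may carry a part. Whether the knockdown itself favours short transcripts, or RNA quality, which was not measured here, adds to the trend, stays open.

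Knockdown replicate 1 lay farther from the controls than the other 2 knockdown libraries in 18 of 22 lists, with Saa3 at 16259 normalized counts against 5068 and 4883. It did not in cardiomyocyte markers (-0.67 against -0.77 and -0.76), in 3 more lists or in C3 (65122 against 70353 and 63913). Lower depth of that library is argued against by its recovered reads, 1.20 times the mean of the other 2. Its excess over them went with the effect that they showed against the controls, with a slope of 0.318 across genes, and a slope of 0.259 was left after the length trend was removed, so length alone is an unlikely source. A larger change of the same kind in that culture, such as a stronger knockdown or inflammatory response, is a candidate explanation that these values allow.

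Of the 10 ways to split the 6 libraries into groups of 3, only the real split, 1 of 10, gave as many called genes (4445), and the highest count of the other 9 splits was 0 in limma, with up to 295 genes at an unadjusted p under 0.05. The genes had been selected by the real split, and 10 splits are too few for a share under 0.05.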
